A study of Homo sapiens with 9 samples.

How the data were processed

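RNA-seq was run on 9 libraries of HEK293T cells, 3 each from cells expressing Halo-RelA, Halo-NfkB1 or the Halo tag alone. Per the labels' protocols, total RNA was purified with DNase treatment and turned into barcoded Illumina TruSeq RNA libraries. The deposited values are FPKM (fragments per kilobase of transcript per M mapped fragments), with a column per library and no pooling. Per the submitters' processing notes the tools were CASAVA 1.8.2, TopHat 1.4.1, Cufflinks 1.3.0 and Cuffdiff 1.0.3 with the hg19 build. Their roles, their settings and the annotation release are not given in the sources used here. Whether counting used strand is not given either, so a gene and its antisense partner cannot be told apart, and reads of overlapping or near-identical genes may be split between them.

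The table held 53437 rows with 53338 distinct Ensembl identifiers, and rows that share an identifier were kept apart. Symbols came from a table of gene names and, for 57 tested rows, from GENCODE release 29, which also gave gene types for 92.8% of tested rows. These references are of another build than hg19, so no coordinates are given. Of 499 list members fixed beforehand, 486 were matched to a row and 413 were tested. Members with no matched row, and matched members below the minimum mean, were not analysed here.

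FPKM are not counts, so no count test was run. Depth was estimated from low values, where a row with 1 fragment in each of a pair of libraries gives their depth ratio, and 28 of 28 pairs checked gave the same ratio within 1%. Of 1082 low rows with a single transcript, 722 (66.7%) had all values at whole multiples of a step, with a tolerance of 0.05. From annotated transcript lengths, the depth of Halo replicate 1 came to 18.9 M fragments (quartiles 18.4 and 19.3 M). The highest depth was 3.71 times the lowest. As fragments per gene were not recovered, no counting intervals are given.

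Rows with a mean of at least 1 FPKM over the 9 libraries were kept (17742 rows, 12989 of them protein-coding). Values were taken as log2(FPKM + 1), so differences are on that scale and understate the change of low genes. All 9 libraries were fitted together with limma 3.58.1 in R 4.3.3, with the group as the only term and 6 residual degrees of freedom, and moderated with an intensity trend. The tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each of the 3 comparisons, with a threshold of 0.05 and no minimum fold. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1. Of tested rows, 1715 were listed at 0 in some library. Such a value can be a failed estimate, and it was kept as listed unless stated.

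There were 24 gene lists, fixed before the data were examined, covering NF-kB genes and targets, stress and interferon responses, p53 targets, the cell cycle, metabolism, histones, HEK293 lineages and markers of haematopoietic cells, fibroblasts, keratinising epithelium and hepatocytes. Lists with at least 3 tested members (23 of 24, all except hepatocyte markers) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which does not compare a list with other genes, were alternatives. The genes named were fixed by rule. They are RELA, NFKB1 and their family, the 10 highest and 10 lowest rows past the threshold in each comparison with a symbol and no overlap between groups, up to 4 members per list with the smallest adjusted p, and otherwise 2 with the highest mean. A selection of these is named.

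The fits were tested on simulated data, with changed genes drawn only among rows with higher means in Halo. The shares found therefore do not cover low rows, such as genes near 0 there. With 200 of the genes changed, the fit found 61.2% of changes of 0.5 on the log2 scale, 85.1% of changes of 1 and 95.5% of changes of 2 for Halo-RelA against Halo, with 14 calls among 17515 unchanged rows. For Halo-NfkB1 against Halo the shares were 61.2%, 88.1% and 97.0%, with 11 calls among 17514. For Halo-RelA against Halo-NfkB1 they were 58.2%, 86.6% and 97.0%, with 13 calls among 17515. A list shifted by -0.3 was found in each of the 3 comparisons, with 0 of 22 other lists called. The simulated noise was independent between genes, so this does not check camera's preset correlation for lists whose members move together.

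Alternatives set before the data were examined were a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, upper-quartile scaling, quantile normalization, the replicate number as a block, the 2 groups of a comparison alone, no trend, each library left out, a minimum fold of 1.5, a threshold of 0.01, an estimated correlation and fry. Protein-coding rows alone, library weights, depth as a covariate, RELA zeros as missing and the family list without RELA and NFKB1 were added after the data were seen. The labels name no batches. Depth estimates and figures used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.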

Results

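The data were RNA-seq libraries of HEK293T cells, a human embryonic kidney cell line that carries the SV40 large T antigen. The cells expressed a fusion of the Halo tag, a protein label used for affinity capture, with RelA (Halo-RelA), a fusion of the tag with the p105 product of NFKB1 (Halo-NfkB1), or the tag alone (Halo). Each of the 3 groups held 3 libraries, 9 in all. RelA and p105 belong to the NF-kB family of transcription factors, and the title of the series names expression changes in networks of transcription factor proteins as the subject. The labels number the replicates without saying whether they were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Values were FPKM for 53437 rows with Ensembl gene identifiers, of which 17742 had a mean of at least 1 and were tested. Depth, estimated from the steps between low values, was 18.9, 60.8 and 34.7 M fragments (M, mega) in Halo replicates 1 to 3. It was 16.4, 26.1 and 42.2 M in the Halo-RelA replicates and 51.0, 28.7 and 18.6 M in the Halo-NfkB1 replicates. The correlation of log2 values across rows was 0.917 to 0.941 within groups, 0.860 to 0.880 between Halo and Halo-RelA and 0.923 to 0.944 between Halo and Halo-NfkB1.

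The transcripts of the fused genes were examined to see what the constructs added. RELA (ENSG00000173039) stood at 255 ± 21.1 FPKM (SD, n = 3) in Halo and at 271 ± 17.2 in Halo-NfkB1. In Halo-RelA it was 79957 and 86832 FPKM in replicates 1 and 2 and was listed at 0 in replicate 3. The mean of the 2 values above 0 was 326 times the Halo mean. NFKB1 (ENSG00000109320) stood at 182 ± 17.2 FPKM in Halo and 252 ± 13.8 in Halo-RelA, a rise of 0.47 ± 0.07 (SE) on the log2 scale with a limma adjusted p of 0.00107. It was listed at 0 in all 3 Halo-NfkB1 libraries. A 0 in such a table can be a failed estimate, so no fold is given for NFKB1 in Halo-NfkB1, and the construct could not be checked there by its own transcript. With all values as listed, the log2 difference of RELA between Halo-RelA and Halo was 2.90 ± 3.95 (SE) and did not pass limma's test (adjusted p = 0.572). Without Halo-RelA replicate 3 it was 8.35 and passed (adjusted p = 2.87e-07).

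**Figure D1:**
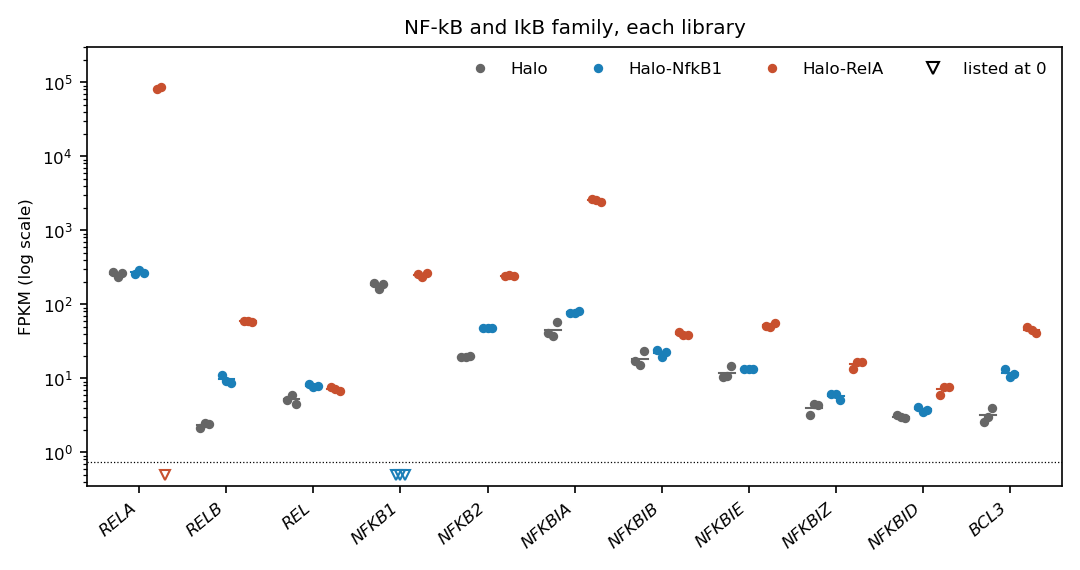
FPKM (log axis) of 11 NF-kB and IkB family genes in each of the 9 libraries, coloured by group, with a short line at the mean of groups that have no value listed at 0. Open triangles below the dotted line mark values listed at 0, which are RELA in Halo-RelA replicate 3 and NFKB1 in the 3 Halo-NfkB1 libraries.

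Expression of Halo-RelA was compared with the tag alone to find transcripts that differ when this activating subunit is expressed. CCL20 (ENSG00000115009), a chemokine for lymphocytes and dendritic cells, went from 0.815 ± 0.149 FPKM (SD, n = 3) in Halo to 609 ± 71.8, a log2 difference of 8.39 ± 0.11 (SE) (adjusted p = 7.39e-09). ICAM1 (ENSG00000090339), an adhesion ligand of leukocyte integrins, went from 0.630 ± 0.206 to 336 ± 6.54 FPKM, and SELE (ENSG00000007908), an endothelial selectin, from 0.445 ± 0.180 to 270.4 ± 21.3. NFKBIA (ENSG00000100906), the inhibitor that holds NF-kB in the cytoplasm, went from 45.1 ± 10.4 to 2563 ± 132 FPKM. The lists of ribosomal, respiration, sterol synthesis and mitosis genes had medians of -0.34, -0.29, -0.51 and -0.41. Their calls by camera ended with an estimated correlation (adjusted p = 0.196, 0.118, 0.0674 and 0.0649).

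After CCL20, ICAM1 and SELE, the next highest log2 differences among the rows named by rule belonged to the cytokine CLCF1 (7.09), the protease inhibitor SERPINA3 (6.93), the growth factor IGF2 (6.82), the cytokine IL32 (6.74), the small heat shock protein HSPB8 (6.24), the glycosyltransferase GALNT9 (6.18) and the costimulatory ligand CD86 (6.18). Of 25 cytokines and chemokines under NF-kB control matched to a row, 13 reached the minimum mean, and all of these rose, also adjusted over the list alone (a median of 3.96, a camera adjusted p = 1.21e-12 and adjusted p = 0.0163 with an estimated correlation). That mean covers all 9 libraries, so a gene near 0 in Halo was kept only where a construct group held it, and the count and the median follow in part from the filter. The median was 1.94 without the filter and 6.05 with a pseudocount of 0.1, and the list passed in both. They included TNF (5.48) and EBI3 (5.04), a subunit of heterodimeric interleukins. Of adhesion molecules, receptors and matrix genes under NF-kB control, 16 rose and 0 fell of 18 measured (16 higher and 0 lower adjusted over the list alone), with a median of 3.15, a camera adjusted p = 1.27e-12 and adjusted p = 0.0495 with an estimated correlation. Only 18 of 22 matched members reached the minimum mean, so these values also follow in part from the filter. Apart from libraries left out, the median ranged from 2.49 to 3.69 over the alternatives. CD40, a receptor of antigen-presenting cells, went up by 6.13 and SDC4, a heparan sulfate proteoglycan, by 3.29. Of NF-kB feedback and survival targets, 17 rose and 1 fell of 22 measured (18 higher and 1 lower adjusted over the list alone), with a median of 1.36, a camera adjusted p = 1.44e-10 and adjusted p = 0.0163 with an estimated correlation. TNFAIP3, a ubiquitin-editing inhibitor of the pathway, rose by 4.43, GADD45B by 4.76, CD83 by 3.28 and the death receptor FAS by 2.22.

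Within the NF-kB and IkB family itself, 10 rose and 0 fell of 11 measured (10 higher and 0 lower adjusted over the list alone), with a median of 2.05, a camera adjusted p = 1.93e-07 and adjusted p = 0.0555 with an estimated correlation. RELB rose by 4.17, NFKB2 by 3.58, BCL3 by 3.49 and NFKBIE by 2.05. The member that did not pass was RELA, because of the value listed at 0. REL rose by 0.40, a call that ended under quantile normalization (adjusted p = 0.168).

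Antigen presentation by MHC class I moved as a group: 16 rose and 0 fell of 17 measured (16 higher and 0 lower adjusted over the list alone), with a median of 1.14, a camera adjusted p = 1.44e-10 and adjusted p = 0.0662 with an estimated correlation. TAPBP, which loads peptides, rose by 3.55, the peptide transporter TAP1 by 2.78, HLA-F by 2.66 and the trimming peptidase ERAP1 by 2.17, with reads of HLA genes possibly split between relatives. Of interferon-stimulated genes, 16 rose and 1 fell of 21 measured (16 higher and 1 lower adjusted over the list alone), with a median of 0.85, a camera adjusted p = 2.60e-06 and adjusted p = 0.0682 with an estimated correlation. The antiviral enzyme OAS3 rose by 3.22, the RNA sensor IFIH1 by 2.64 and IFITM1 by 1.16. Of immediate-early and AP-1 genes, 14 rose and 1 fell of 18 measured (14 higher and 1 lower adjusted over the list alone), with a median of 2.41, a camera adjusted p = 4.74e-08 and adjusted p = 0.149 with an estimated correlation. FOSB rose by 4.57, MAFF by 4.36, EGR1 by 3.82 and EGR3 by 3.69. Genes of the unfolded protein and integrated stress response followed, where 12 rose and 2 fell of 21 measured (13 higher and 2 lower adjusted over the list alone), with a median of 0.43, a camera adjusted p = 0.00790 and adjusted p = 0.413 with an estimated correlation. Its examples were the phosphatase subunit PPP1R15A (1.38) and the transcription factor XBP1 (1.01).

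Of markers of other cell types matched to a row, 16 haematopoietic, 14 fibroblast and 14 keratinising epithelial, only 5, 6 and 6 reached the minimum mean, some of them through their Halo-RelA values alone. The values given for these lists are therefore set in part by the filter. Without it their medians were 0.28, 0.55 and 0.67, and the 3 lists passed. Of haematopoietic markers, 3 rose and 0 fell of 5 measured (3 higher and 0 lower adjusted over the list alone), with a median of 1.15, a camera adjusted p = 0.00790 and adjusted p = 0.118 with an estimated correlation. LCP1, an actin-bundling protein of leukocytes, went from 1.03 ± 0.218 to 26.5 ± 2.32 FPKM and the integrin ITGAM from 0.658 ± 0.219 to 4.71 ± 1.90. Of fibroblast markers, 5 rose and 0 fell of 6 measured (6 higher and 0 lower adjusted over the list alone), with a median of 1.14, a camera adjusted p = 0.000869 and adjusted p = 0.0649 with an estimated correlation. Fibronectin (FN1) went from 45.0 ± 2.99 to 351 ± 14.4 FPKM and the collagen chain COL1A1 from 14.7 ± 1.56 to 33.6 ± 3.83. Of keratinising epithelial markers, 5 rose and 0 fell of 6 measured (5 higher and 0 lower adjusted over the list alone), with a median of 1.4, a camera adjusted p = 0.000553 and adjusted p = 0.0674 with an estimated correlation. The keratin KRT6A, listed at 0 in the 3 Halo libraries, stood at 5.57 ± 1.05. For hepatocyte markers only transferrin (TF) was measured, at 1.71 ± 0.106 FPKM in Halo and 1.19 ± 0.163 in Halo-RelA, and it did not pass (adjusted p = 0.0846). It did pass under quantile normalization (adjusted p = 0.0171), with protein-coding rows alone (0.0379), with library weights (0.0383) and with the 2 groups alone (0.0261). Markers of the neuronal and renal lineages of HEK293 went both ways, where 2 rose and 6 fell of 10 measured (2 higher and 6 lower adjusted over the list alone), with a median of -0.34, a camera adjusted p = 0.292 and adjusted p = 0.558 with an estimated correlation. The list passed as lower in fry, which asks whether genes move on balance (adjusted p = 0.0250). The kidney transcription factor PAX2 rose by 1.53 and the neurofilament NEFM by 1.07, while EYA1 had a log2 difference of -1.19.

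Lower in Halo-RelA were the cytosolic ribosomal proteins, where 0 rose and 26 fell of 28 measured (0 higher and 26 lower adjusted over the list alone), with a median of -0.34, a camera adjusted p = 4.74e-08 and adjusted p = 0.196 with an estimated correlation. RPLP0 went from 1838 ± 62.4 to 1293 ± 31.6 FPKM. Of nuclear-encoded oxidative phosphorylation genes, 1 rose and 23 fell of 26 measured (1 higher and 23 lower adjusted over the list alone), with a median of -0.29, a camera adjusted p = 2.93e-06 and adjusted p = 0.118 with an estimated correlation. The ATP synthase subunit ATP5F1A had a log2 difference of -0.51 and the complex I subunit NDUFA2 of -0.50. Under quantile normalization the ribosomal and oxidative phosphorylation medians were -0.15 and -0.19, and both lists passed. The median of all rows was then -0.13, so relative to it these medians were -0.017 and -0.059, against -0.27 and -0.22 as deposited. Of cholesterol biosynthesis and uptake genes, 0 rose and 18 fell of 22 measured (0 higher and 18 lower adjusted over the list alone), with a median of -0.51, a camera adjusted p = 7.94e-07 and adjusted p = 0.0674 with an estimated correlation. The values were -1.33 for IDI1, -1.14 for squalene epoxidase (SQLE) and -1.12 for DHCR7. Of G2 and mitosis genes, 0 rose and 21 fell of 24 measured (0 higher and 21 lower adjusted over the list alone), with a median of -0.41, a camera adjusted p = 1.23e-06 and adjusted p = 0.0649 with an estimated correlation. The topoisomerase TOP2A had -0.61, the mitotic kinesin KIF11 -0.57 and the anaphase activator CDC20 -0.69. Of S phase and DNA replication genes, 3 rose and 14 fell of 23 measured (3 higher and 14 lower adjusted over the list alone), with a median of -0.23, a camera adjusted p = 0.00535 and adjusted p = 0.304 with an estimated correlation. The helicase subunit MCM4 had -0.62, while the cyclin CCNE2 rose by 1.63. The S phase call ended under quantile normalization (adjusted p = 0.207).

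Genes known as p53 targets were lower on balance in Halo-RelA, where 3 rose and 12 fell of 20 measured (3 higher and 12 lower adjusted over the list alone), with a median of -0.64, a camera adjusted p = 0.0295 and adjusted p = 0.304 with an estimated correlation. The repair gene DDB2 had a log2 difference of -1.43, AEN of -0.97, TP53INP1 of -0.83 and TIGAR of -0.64, while PMAIP1 rose by 1.01 and BTG2 by 0.99. That list call ended with a minimum mean of 5 FPKM (adjusted p = 0.0906), under quantile normalization (0.0948) and with the 2 groups alone (0.0506). Of glycolysis and hypoxia genes, 6 rose and 14 fell of 23 measured (6 higher and 14 lower adjusted over the list alone), with a median of -0.38, a camera adjusted p = 0.04995 and adjusted p = 0.416 with an estimated correlation. GAPDH had -0.74 and LDHA -0.59, while ADM rose by 1.73. The call ended with a minimum mean of 5 FPKM (adjusted p = 0.165), a pseudocount of 0.1 (0.0518), protein-coding rows alone (0.0581), depth as a covariate (0.0515) and the 2 groups alone (0.0651). It also ended under quantile normalization (adjusted p = 0.283) and without Halo replicate 1 (0.0637), Halo replicate 3 (0.0521) or Halo-RelA replicate 3 (0.0898). On the 16468 rows with a length and a GC value the glycolysis list did not pass (adjusted p = 0.0530), and it passed there once a trend on length (0.0317), on GC content (0.0260) or on both (0.0263) was removed. Of histone genes, 2 rose and 8 fell of 12 measured (2 higher and 8 lower adjusted over the list alone), with a median of -0.51, a camera adjusted p = 0.0349 and adjusted p = 0.304 with an estimated correlation, and this call ended with a minimum mean of 5 FPKM (0.0682), under quantile normalization (0.164) and without Halo replicate 3 (0.0745). It also ended once a trend on length (0.0644) or on length and GC content (0.0579) was removed, on rows where it passed before (adjusted p = 0.0379). H2AC6 had a log2 difference of -1.21, although reads of histone genes may be split between near-identical copies.

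Proteasome subunits moved least among the lists past the threshold in Halo-RelA, where 2 rose and 8 fell of 25 measured (2 higher and 7 lower adjusted over the list alone), with a median of -0.11, a camera adjusted p = 0.0253 and adjusted p = 0.413 with an estimated correlation. PSMA7 had a log2 difference of -0.58. The call ended with a minimum mean of 5 FPKM (adjusted p = 0.0906), with upper-quartile scaling (0.0916) and without Halo-RelA replicate 2 (0.0590), and its test direction turned under quantile normalization (0.557). It also ended once a trend on length (0.236), on GC content (0.148) or on both (0.415) was removed. Heat shock and cytosolic chaperone genes did not pass as a list (a median of 0.08, a camera adjusted p = 0.189 and adjusted p = 0.558 with an estimated correlation), with 8 higher and 4 lower of 19 measured (8 higher and 4 lower adjusted over the list alone), and did pass under quantile normalization (0.00782) and in fry (0.0144). The co-chaperone DNAJA1 rose by 0.82 and the mitochondrial chaperonin HSPD1 had -0.42. Genes of the IKK complex and receptor-proximal signalling did not pass as a list either (a median of 0.15, a camera adjusted p = 0.0749 and adjusted p = 0.151 with an estimated correlation), with 8 higher and 4 lower of 22 measured (8 higher and 4 lower adjusted over the list alone), and did pass in fry (5.80e-05). The median of that list was 0.086 without Halo-RelA replicate 1 and 0.061 under quantile normalization. Among them the receptor TNFRSF1A rose by 0.84 and the kinase adaptor TAB2 by 0.80.

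In limma's test 9031 of the 17742 rows differed between Halo-RelA and Halo, 4065 higher and 4966 lower. The balance turned to 4470 higher and 4291 lower with upper-quartile scaling and to 6238 and 4691 without the filter on low values. On the 16468 rows with a length and a GC value it was 4013 higher and 4945 lower, and it turned to 4387 and 4257 there after a length trend was removed and to 4630 and 4415 after a GC trend was removed. At least 2-fold differences were mostly rises, with 1576 rows higher and 175 lower, and at least 8-fold there were 246 and 15. The groups did not overlap in 58.9% of rows, where chance gives 10%. With a minimum fold of 1.5 the count was 3592. By camera 20 of 23 lists passed, 11 higher and 9 lower, and 3 of them held with an estimated correlation.

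Expression of Halo-NfkB1 was compared with the tag alone in the same way, and fewer rows differed. Heat-inducible chaperone genes were among the highest rises. HSPA6 (ENSG00000173110), a strictly stress-inducible chaperone, went from 0.0767 ± 0.0289 FPKM (SD, n = 3) to 15.6 ± 3.56, a log2 difference of 3.92 ± 0.16 (SE) (adjusted p = 3.79e-05). HSPA1B (ENSG00000204388) went from 51.3 ± 4.13 to 253 ± 16.7 FPKM, although reads of this gene and its near-identical neighbour HSPA1A may be split between them. The stress cytokine GDF15 (ENSG00000130513) went from 4.73 ± 0.808 to 20.4 ± 2.13 FPKM and the adhesion molecule NECTIN4 (ENSG00000143217) from 2.81 ± 0.348 to 14.1 ± 1.64. The lists of sterol synthesis, glycolysis, respiration and ribosomal genes had medians of -0.32, -0.37, -0.27 and -0.30. Their calls by camera ended with an estimated correlation (adjusted p = 0.0653, 0.106, 0.0653 and 0.106).

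Of heat shock and cytosolic chaperone genes in Halo-NfkB1, 11 rose and 2 fell of 19 measured (11 higher and 2 lower adjusted over the list alone), with a median of 0.34, a camera adjusted p = 2.41e-07 and adjusted p = 0.106 with an estimated correlation. The co-chaperone DNAJB1 rose by 1.17 and HSPH1 by 0.56. Of p53 target genes, 15 rose and 1 fell of 20 measured (16 higher and 1 lower adjusted over the list alone), with a median of 0.50, a camera adjusted p = 2.83e-11 and adjusted p = 0.0653 with an estimated correlation. The antiproliferative gene BTG2 rose by 1.4, the kinase PLK2 by 1.36, the cyclin-dependent kinase inhibitor CDKN1A by 0.90 and TP53INP1 by 0.78. Of unfolded protein and integrated stress response genes, 8 rose and 1 fell of 21 measured (9 higher and 1 lower adjusted over the list alone), with a median of 0.22, a camera adjusted p = 2.16e-05 and adjusted p = 0.236 with an estimated correlation. PPP1R15A rose by 1.19 and SESN2 by 1.09, and PDIA6, a disulfide isomerase, had -0.30. Of immediate-early and AP-1 genes, 9 rose and 1 fell of 18 measured (16 higher and 1 lower adjusted over the list alone), with a median of 0.45, a camera adjusted p = 2.81e-07 and adjusted p = 0.178 with an estimated correlation. FOSL1 rose by 1.19 and JUN by 0.69, and MYC had -0.54.

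Several NF-kB genes rose with Halo-NfkB1 as well. In the NF-kB and IkB family, 5 rose and 1 fell of 11 measured (6 higher and 1 lower adjusted over the list alone), with a median of 0.45, a camera adjusted p = 0.000115 and adjusted p = 0.106 with an estimated correlation. The single fall was NFKB1, listed at 0. Because of it the mean of the list was -0.04 while the median was above 0, and fry gave the direction down (adjusted p = 0.114). Without the RELA and NFKB1 values the median was 0.52 and fry gave the direction up. RELB rose by 1.67, BCL3 by 1.62, NFKB2 by 1.25, NFKBIA by 0.80 and REL by 0.52. Of NF-kB feedback and survival targets, 7 rose and 0 fell of 22 measured (8 higher and 0 lower adjusted over the list alone), with a median of 0.21, a camera adjusted p = 0.000115 and adjusted p = 0.0653 with an estimated correlation. That median was 0.13 under quantile normalization. FAS rose by 1.00, GADD45B by 0.92, CD83 by 0.79 and the deubiquitinase CYLD by 0.75, while TNFAIP3 had 0.17 and did not pass.

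Of cytokines and chemokines under NF-kB control in Halo-NfkB1, 3 rose and 0 fell of 13 measured (3 higher and 0 lower adjusted over the list alone), with a median of 0.17, a camera adjusted p = 0.00122 and adjusted p = 0.106 with an estimated correlation. Over the alternatives the median ranged from 0.08 under quantile normalization to 0.49 with a pseudocount of 0.1. The rises were CSF1 (1.44), IL32 (1.04) and EBI3 (0.35). The EBI3 call ended without the filter on low values (adjusted p = 0.0764), with a minimum mean of 5 FPKM (0.188) and with the replicate number as a block (0.0573). It also ended without Halo replicate 1 (adjusted p = 0.0526), without Halo-NfkB1 replicate 3 (0.0663) and under quantile normalization (0.532). CCL20 stood at 1.14 ± 0.210 FPKM and did not pass (limma adjusted p = 0.189). Of adhesion, receptor and matrix genes under NF-kB control, 4 rose and 0 fell of 18 measured (5 higher and 0 lower adjusted over the list alone), with a median of 0.12, a camera adjusted p = 0.00335 and adjusted p = 0.232 with an estimated correlation. The median was 0.19 without Halo replicate 1, 0.07 without Halo replicate 2, 0.06 under quantile normalization and 0.25 with a pseudocount of 0.1. CD70 rose by 0.92 and the transcription factor IRF1 by 0.81. Of IKK complex and receptor-proximal genes, 4 rose and 0 fell of 22 measured (6 higher and 0 lower adjusted over the list alone), with a median of 0.09, a camera adjusted p = 0.0149 and adjusted p = 0.106 with an estimated correlation, and TAB2 rose by 0.35. The median of that list was 0.15 without Halo replicate 3 and 0.04 without Halo-NfkB1 replicate 2. Of MHC class I antigen presentation genes, 8 rose and 0 fell of 17 measured (10 higher and 2 lower adjusted over the list alone), with a median of 0.15, a camera adjusted p = 2.35e-06 and adjusted p = 0.127 with an estimated correlation. ERAP1 rose by 1.75, TAPBP by 1.21 and TAP1 by 0.75. Of interferon-stimulated genes, 4 rose and 1 fell of 21 measured (5 higher and 2 lower adjusted over the list alone), with a median of 0.18, a camera adjusted p = 0.0160 and adjusted p = 0.272 with an estimated correlation. OAS3 rose by 0.86. That list call ended with a minimum mean of 5 FPKM (adjusted p = 0.0683), in fry (0.0581), without Halo replicate 2 (0.0901, with a median of 0.09) and under quantile normalization (0.0883).

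Lower in Halo-NfkB1 were cholesterol biosynthesis and uptake genes, where 0 rose and 15 fell of 22 measured (0 higher and 18 lower adjusted over the list alone), with a median of -0.32, a camera adjusted p = 1.52e-09 and adjusted p = 0.0653 with an estimated correlation. SQLE had a log2 difference of -0.68, IDI1 of -0.65 and INSIG1, a sterol-regulated brake on the pathway, of -0.76. Of glycolysis and hypoxia genes, 1 rose and 15 fell of 23 measured (2 higher and 17 lower adjusted over the list alone), with a median of -0.37, a camera adjusted p = 8.17e-08 and adjusted p = 0.106 with an estimated correlation. LDHA had -0.60, TPI1 -0.47 and ENO1 -0.45. Of ribosomal protein genes, 0 rose and 23 fell of 28 measured (0 higher and 25 lower adjusted over the list alone), with a median of -0.30, a camera adjusted p = 2.01e-15 and adjusted p = 0.106 with an estimated correlation, and RPL22 had -0.51. Of oxidative phosphorylation genes, 0 rose and 18 fell of 26 measured (0 higher and 25 lower adjusted over the list alone), with a median of -0.27, a camera adjusted p = 4.72e-13 and adjusted p = 0.0653 with an estimated correlation, and the ATP synthase subunit ATP5PO had -0.46. Of proteasome subunits, 0 rose and 12 fell of 25 measured (1 higher and 15 lower adjusted over the list alone), with a median of -0.16, a camera adjusted p = 2.35e-06 and adjusted p = 0.159 with an estimated correlation, and PSMB7 had -0.35. Under quantile normalization the medians of the ribosomal, oxidative phosphorylation and proteasome lists were -0.19, -0.17 and -0.06, and the 3 lists passed. Relative to the median of all rows, the proteasome median was -0.14 as deposited and -0.04 under quantile normalization.

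Cell cycle, histone and marker lists did not pass in Halo-NfkB1 with a minimum mean of 1 FPKM and the values as deposited, while the G2 and S phase lists passed elsewhere. For G2 and mitosis genes the list had a median of 0.02, a camera adjusted p = 0.419 and adjusted p = 0.632 with an estimated correlation, with 2 higher and 1 lower of 24 measured (2 higher and 1 lower adjusted over the list alone). Under quantile normalization this list did pass, with a median of 0.08 (adjusted p = 0.00454), as it did once trends on length and GC content were removed (0.0441). For S phase and DNA replication it had a median of -0.05, a camera adjusted p = 0.184 and adjusted p = 0.599 with an estimated correlation, with 0 higher and 2 lower of 23 measured (2 higher and 8 lower adjusted over the list alone). Without the filter on low values it did pass as lower (adjusted p = 0.0284), while under quantile normalization its median was 0.032. Histone genes had a median of -0.004, a mean of 0.05 and a camera adjusted p of 0.955, with 1 higher and 1 lower of 12 measured (1 higher and 1 lower adjusted over the list alone). The HEK293 lineage list had a median of -0.09, a camera adjusted p = 0.181 and adjusted p = 0.464 with an estimated correlation, with 0 higher and 2 lower of 10 measured (0 higher and 4 lower adjusted over the list alone). Haematopoietic markers had a median of 0.19, a camera adjusted p = 0.155 and adjusted p = 0.324 with an estimated correlation, with 0 higher and 0 lower of 5 measured (0 higher and 0 lower adjusted over the list alone). Fibroblast markers had a median of 0.07, a camera adjusted p = 0.362 and adjusted p = 0.464 with an estimated correlation, with 1 higher and 0 lower of 6 measured (1 higher and 0 lower adjusted over the list alone). Keratinising epithelial markers had a median of 0.07, a camera adjusted p = 0.292 and adjusted p = 0.464 with an estimated correlation, with 1 higher and 0 lower of 6 measured (1 higher and 0 lower adjusted over the list alone). Over fits that left out 1 library each, the medians ranged from -0.0058 to 0.037 for G2, -0.087 to -0.021 for S phase, -0.073 to 0.0030 for histones and -0.14 to -0.075 for HEK293 lineages. They ranged from 0.11 to 0.30 for haematopoietic, 0.014 to 0.20 for fibroblast and 0.033 to 0.13 for keratinising markers. FN1 stood at 46.0 ± 3.10 FPKM, LCP1 at 1.31 ± 0.229 and transferrin (TF) at 2.68 ± 0.542, where it did not pass (adjusted p = 0.0634). Transferrin did pass without an intensity trend (adjusted p = 0.0418), with protein-coding rows alone (0.0221), with library weights (0.0432) and without Halo-NfkB1 replicate 2 (0.0264).

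In limma's test 2901 of the 17742 rows differed between Halo-NfkB1 and Halo, 1111 higher and 1790 lower, with 55 rows higher and 8 lower by at least 2-fold. Upper-quartile scaling turned the split to 1541 higher and 1237 lower. Without single libraries it also moved, to 491 higher without Halo-NfkB1 replicate 1 (31.4% of the calls) and 834 lower without Halo-NfkB1 replicate 3, with a share higher of 45.2% without Halo-NfkB1 replicate 2, against 38.3% with all libraries. The groups did not overlap in 34.6% of rows, where chance gives 10%. The count was 1585 without Halo replicate 1, 1562 without Halo-NfkB1 replicate 1 and 1358 without Halo-NfkB1 replicate 3. It was 306 with a minimum fold of 1.5, 816 at a threshold of 0.01 and 1764 with the 2 groups alone. By camera 16 of 23 lists passed, 11 higher and 5 lower. With an estimated correlation camera passed 0 of them, with 10 at an unadjusted p under 0.05, and fry passed 14.

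**Figure D2:**
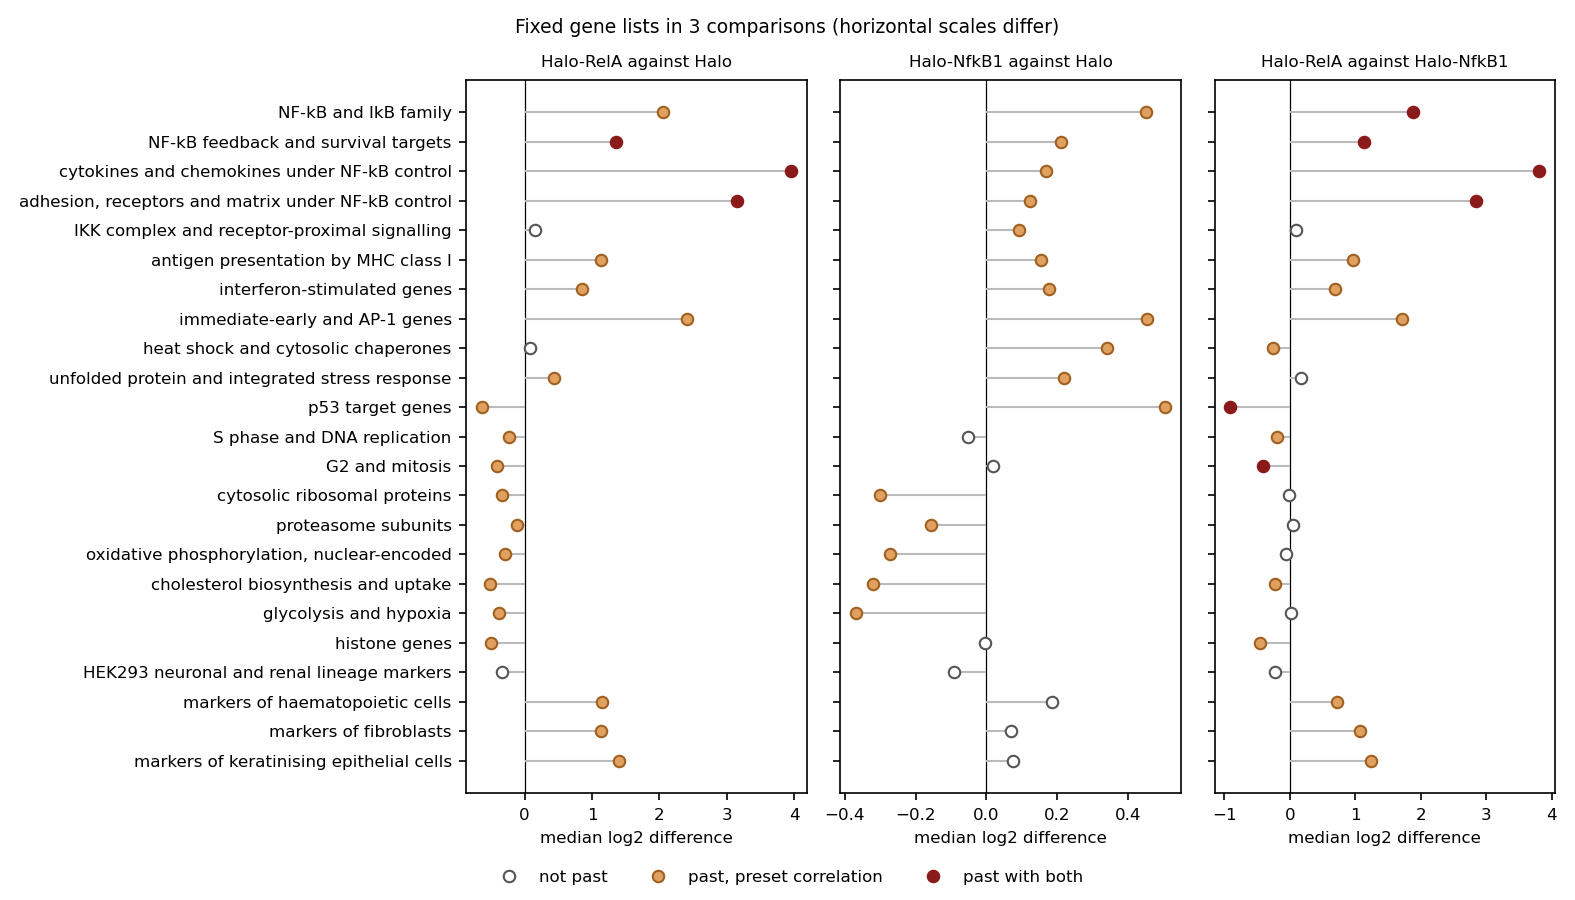
Median log2 difference of the members of 23 fixed gene lists in the 3 comparisons, with a separate horizontal scale for each. Filled points passed camera's adjusted threshold of 0.05, darker where they also did with an estimated correlation, and open points did not pass. The p53 list lies at -0.64 with Halo-RelA and at 0.50 with Halo-NfkB1, and the fall of the proteasome list with Halo-RelA turned under quantile normalization.

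The construct groups were compared directly to test the difference between them itself. The NF-kB lists were higher in Halo-RelA. The 13 of 25 cytokines and chemokines that reached the minimum mean were all higher, also adjusted over the list alone (a median of 3.81, a camera adjusted p = 3.58e-13 and adjusted p = 0.0155 with an estimated correlation), led by CCL20 at 8.15 ± 0.11 (SE). Their selection by a mean that includes Halo-RelA sets part of this, and the median was 1.15 without the filter and 5.83 with a pseudocount of 0.1. Also higher were all 18 measured adhesion, receptor and matrix genes, also adjusted over the list alone (a median of 2.85, a camera adjusted p = 3.58e-13 and adjusted p = 0.0430 with an estimated correlation), led by ICAM1 at 7.57 and SELE at 7.50. The filter kept these 18 of 22 matched members in part through Halo-RelA. Apart from libraries left out, the median ranged from 2.10 to 3.20 over the alternatives. STAT5A, a cytokine-responsive transcription factor, was at 84.1 ± 1.12 FPKM (SD, n = 3) against 0.218 ± 0.0592 and the protease inhibitor SERPINA3 at 173 ± 6.07 against 0.666 ± 0.325. The heat shock gene HSPA6 was lower in Halo-RelA by a log2 difference of -3.12 ± 0.16 (SE) (adjusted p = 3.12e-06) and NECTIN4 by -3.13 ± 0.16 (SE).

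Of p53 target genes in the direct comparison, 1 were higher and 18 lower of 20 measured (1 higher and 18 lower adjusted over the list alone), with a median of -0.91, a camera adjusted p = 1.70e-08 and adjusted p = 0.0485 with an estimated correlation. DDB2 had a log2 difference of -1.75, TP53INP1 of -1.61, AEN of -1.36 and CDKN1A of -0.76, whereas PMAIP1 was higher by 0.92. Of heat shock and cytosolic chaperone genes, 1 were higher and 10 lower of 19 measured (1 higher and 12 lower adjusted over the list alone), with a median of -0.26, a camera adjusted p = 0.000369 and adjusted p = 0.232 with an estimated correlation. DNAJB1 had -0.98 and HSPA1B -1.12. Of G2 and mitosis genes, 0 were higher and 19 lower of 24 measured (0 higher and 20 lower adjusted over the list alone), with a median of -0.41, a camera adjusted p = 4.21e-08 and adjusted p = 0.0485 with an estimated correlation. CDC20 had -0.92 and HMMR, a spindle protein, -0.81. Of S phase genes, 3 were higher and 13 lower of 23 measured (3 higher and 13 lower adjusted over the list alone), with a median of -0.20, a camera adjusted p = 0.00677 and adjusted p = 0.352 with an estimated correlation. Of histone genes, 2 were higher and 8 lower of 12 measured (2 higher and 8 lower adjusted over the list alone), with a median of -0.45, a camera adjusted p = 0.0157 and adjusted p = 0.273 with an estimated correlation. Of cholesterol genes, 2 were higher and 12 lower of 22 measured (2 higher and 14 lower adjusted over the list alone), with a median of -0.22, a camera adjusted p = 0.0136 and adjusted p = 0.281 with an estimated correlation. HSD17B7 had -1.27 and INSIG1 was higher by 0.65. The S phase, histone and cholesterol calls ended under quantile normalization (adjusted p = 0.0655, 0.0584 and 0.0551).

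Also higher in Halo-RelA than in Halo-NfkB1 were NF-kB feedback and survival targets, with a median of 1.14, a camera adjusted p = 5.94e-09 and adjusted p = 0.0155 with an estimated correlation. There 17 were higher and 1 lower of 22 measured (17 higher and 1 lower adjusted over the list alone), with TNFAIP3 at 4.27 and TRAF1 at 2.37. In the NF-kB and IkB family, 9 were higher and 0 lower of 11 measured (9 higher and 0 lower adjusted over the list alone), with a median of 1.88, a camera adjusted p = 1.0e-06 and adjusted p = 0.0485 with an estimated correlation, which includes the NFKB1 values listed at 0. For MHC class I antigen presentation, 16 were higher and 0 lower of 17 measured (16 higher and 0 lower adjusted over the list alone), with a median of 0.97, a camera adjusted p = 5.31e-10 and adjusted p = 0.0592 with an estimated correlation. For interferon-stimulated genes, 17 were higher and 1 lower of 21 measured (17 higher and 1 lower adjusted over the list alone), with a median of 0.69, a camera adjusted p = 6.10e-06 and adjusted p = 0.0766 with an estimated correlation. For immediate-early and AP-1 genes, 14 were higher and 2 lower of 18 measured (14 higher and 2 lower adjusted over the list alone), with a median of 1.71, a camera adjusted p = 9.73e-07 and adjusted p = 0.216 with an estimated correlation. Haematopoietic markers had a median of 0.72, a camera adjusted p = 0.0192 and adjusted p = 0.181 with an estimated correlation, with 3 higher and 0 lower of 5 measured (3 higher and 0 lower adjusted over the list alone), a call that ended under quantile normalization (0.0539). Fibroblast markers had a median of 1.07, a camera adjusted p = 0.00119 and adjusted p = 0.0575 with an estimated correlation, with 5 higher and 0 lower of 6 measured (5 higher and 0 lower adjusted over the list alone). Keratinising epithelial markers had a median of 1.24, a camera adjusted p = 0.000541 and adjusted p = 0.0592 with an estimated correlation, with 6 higher and 0 lower of 6 measured (6 higher and 0 lower adjusted over the list alone). Without the filter, which kept 5 of 16, 6 of 14 and 6 of 14 matched members in part through their Halo-RelA values, the medians of these 3 lists were 0.22, 0.40 and 0.67.

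Lists without a difference past camera's threshold between Halo-RelA and Halo-NfkB1 were ribosomal proteins (a median of -0.02, a camera adjusted p = 0.551 and adjusted p = 0.859 with an estimated correlation), with 2 higher and 3 lower of 28 measured (0 higher and 1 lower adjusted over the list alone), and oxidative phosphorylation (a median of -0.06, a camera adjusted p = 0.482 and adjusted p = 0.769 with an estimated correlation), with 3 higher and 4 lower of 26 measured (3 higher and 2 lower adjusted over the list alone). Proteasome subunits had a median of 0.05, a camera adjusted p = 0.271 and adjusted p = 0.736 with an estimated correlation, with 5 higher and 2 lower of 25 measured (3 higher and 1 lower adjusted over the list alone), and passed under quantile normalization (adjusted p = 0.0251). Glycolysis and hypoxia genes had a median of 0.02, a camera adjusted p = 0.482 and adjusted p = 0.769 with an estimated correlation, with 6 higher and 5 lower of 23 measured (7 higher and 5 lower adjusted over the list alone), and passed in fry (0.0412). NDRG1 was higher by 1.35 and SLC2A3, a glucose transporter, by 1.21. Unfolded protein and integrated stress response genes had a median of 0.17, a camera adjusted p = 0.371 and adjusted p = 0.769 with an estimated correlation, with 7 higher and 4 lower of 21 measured (7 higher and 4 lower adjusted over the list alone), and a median of 0.0043 without Halo-NfkB1 replicate 2 and 0.25 without Halo-NfkB1 replicate 1. IKK complex and receptor-proximal genes had a median of 0.09, a camera adjusted p = 0.371 and adjusted p = 0.424 with an estimated correlation, with 6 higher and 4 lower of 22 measured (6 higher and 5 lower adjusted over the list alone), and passed in fry (0.00131). Their median was -0.067 under quantile normalization. The HEK293 lineage list had a median of -0.23, a camera adjusted p = 0.371 and adjusted p = 0.707 with an estimated correlation, with 2 higher and 5 lower of 10 measured (2 higher and 5 lower adjusted over the list alone), and its mean of 0.04 had the opposite sign to its median. Over fits that left out 1 library each, the medians ranged from -0.042 to 0.0085 for ribosomal proteins, -0.074 to -0.039 for oxidative phosphorylation, 0.041 to 0.086 for the proteasome and -0.021 to 0.035 for glycolysis and hypoxia. Transferrin, the only hepatocyte marker measured, was lower in Halo-RelA by a log2 difference of -0.74 (adjusted p = 0.00263).

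In limma's test 7848 of the 17742 rows differed between Halo-RelA and Halo-NfkB1, 3954 higher and 3894 lower in Halo-RelA, of which 1405 and 201 did so by at least 2-fold. Without the filter on low values 5904 were higher and 3789 lower, and under quantile normalization 3537 were higher and 5067 lower. The groups did not overlap in 56.7% of rows, where chance gives 10%. With a minimum fold of 1.5 the count was 3206. By camera 16 of 23 lists passed, 10 higher and 6 lower, and 6 of them held with an estimated correlation.

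Rows that moved the same way with both constructs were counted to see what the groups had in common. RELB, BCL3, NFKB2, ERAP1, TAPBP, FAS and PPP1R15A were higher than Halo in both. SQLE, IDI1, LDHA, GAPDH and RPLP0 were lower in both. In all, 633 rows were higher in both, where independent lists of these sizes would share 255, and 1355 were lower in both, where independent lists would share 501. In 50 simulations of unchanged groups against the same controls, the mean was 0 rows higher in both and 0.04 lower in both, as almost no row is called in unchanged groups, so these counts do not measure sharing. Of the 633, 356 were further up with Halo-RelA in the direct test, 24 further up with Halo-NfkB1 and 253 did not pass it. Of the 1355, the numbers were 465, 49 and 841. Another 90 rows were higher with Halo-RelA and lower with Halo-NfkB1, NFKB1 among them, and 134 were the reverse, such as NECTIN4, DDB2 and TP53INP1, where independent lists would share 410 and 311.

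The log2 differences of the construct groups had the same sign in 64.9% of rows, against 66.6% in the simulations, and a correlation across rows of 0.333 against 0.50, and genes are not independent replicates. Their covariance was 0.158 against a simulated 0.0821, a difference of 0.0759. The 3 control libraries are too few to be divided, so part of the overlap and of the covariance may come from the shared controls. The count of 633 was 351 without Halo replicate 1, 312 without Halo-NfkB1 replicate 1 and 348 without Halo-NfkB1 replicate 3. The count of 1355 was 784, 837 and 689 without the same libraries.

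**Figure D3:**
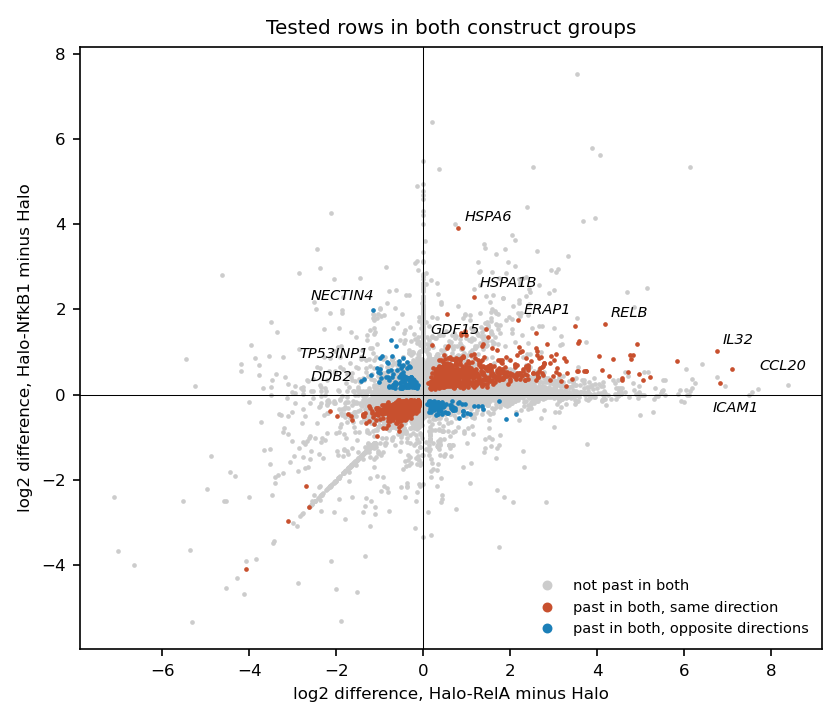
Log2 difference from Halo in Halo-RelA (horizontal) and Halo-NfkB1 (vertical) for each tested row, without RELA and NFKB1. Red points passed limma's threshold in both comparisons with the same direction and blue points with opposite directions. NECTIN4, DDB2 and TP53INP1 lie at upper left, and CCL20 and ICAM1 at the right edge near 0 on the vertical axis.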

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

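The tests of the values listed at 0 and of the shared Halo libraries were chosen only after the result was seen, as was the division of the scaling test by comparison.

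The list of p53 target genes had a median log2 difference of -0.91 between Halo-RelA and Halo-NfkB1, which passed also with an estimated correlation (adjusted p = 0.0485). Against Halo its medians had opposite signs, and both calls ended there (adjusted p = 0.304 for Halo-RelA and 0.0653 for Halo-NfkB1 with an estimated correlation). With relative depth as a covariate the median was -0.91 (adjusted p = 2.82e-08), and after trends on transcript length and GC content were removed it was -0.91, so the tables argue against depth and these trends as the whole cause. Leaving out each of the 6 libraries in turn, the median ranged from -0.95 to -0.88, which argues against a single library. The largest adjusted p by camera was then 5.76e-08. This p and that of the depth fit were at the preset correlation, where lists also passed in other splits of the libraries. These fits were not run with an estimated correlation. A difference between the constructs in their effect on these genes is a hypothesis that stays open, found and tested on the same data. The values are of transcripts on a list, and whether p53 itself had a part was not tested.

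In all, 224 rows, or 223 without NFKB1, were called in opposite directions against Halo in the construct groups, and all 224 passed the direct test. Their direct difference adds changes already called against the same controls, so passing was all but fixed and adds no support.

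RELA was listed at 0 in Halo-RelA replicate 3 and NFKB1 in every Halo-NfkB1 library. If replicate 3 held RELA at the mean of the other 2, the fragments implied there would be 1.55 times those of replicate 2, the higher of the others, and 11.2 against 7.22 and 4.17 M. This is in line with an estimator that gave no value where too many fragments fell, but it follows from that library being the deepest of 3 and rests on this library alone. A library of another group under that label is argued against, as 9 other family members there had a median log2 difference of 2.14 from Halo, beside 2.04 and 1.97 in replicates 1 and 2. For NFKB1 no library gave a value, so this could not be tested.

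Ribosomal protein and oxidative phosphorylation genes were lower in both construct groups and did not pass the direct test. With the length trend removed the ribosomal median in Halo-NfkB1 was -0.23, and with the GC trend removed -0.27, both lists staying past the threshold, so neither trend is the whole cause. Scaling as the whole cause was argued against for Halo-NfkB1, where upper-quartile scaling and quantile normalization left at least 0.581 of the medians relative to all rows. Quantile normalization still removed part of them, so a part through scaling stays open. In Halo-RelA, RELA alone would take 25.5% and 27.6% of the estimated fragments of replicates 1 and 2. If this lowered all other rows by a common factor, upper-quartile scaling would take it out. That scaling left 0.974 of the ribosomal and 0.969 of the oxidative phosphorylation median relative to all rows. This argues against a common factor as the whole cause for these lists. Scaling of other kinds was not settled for this group. Quantile normalization there left 0.0625 of the ribosomal and 0.268 of the oxidative phosphorylation median, while upper-quartile scaling left 0.974 of the ribosomal median. Quantile normalization gives all libraries the same distribution, but 1576 rows were at least 2-fold higher in Halo-RelA and 175 lower. It can therefore also take out differences of the group itself, and does not decide this. An effect of both constructs and a departure of the shared Halo libraries cannot be told apart, because there is 1 control group and the ribosomal median differed by -0.017 between the constructs. None of these list calls held with an estimated correlation.

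Other splits of the libraries were counted for each comparison. With 3 against 3 there are 10 splits, too few for a share under 0.05. Halo-RelA against Halo gave 9031 rows and the highest other split 9, in 1 of 10 splits as many. Halo-NfkB1 against Halo gave 2901 and 17, and Halo-RelA against Halo-NfkB1 gave 7848 and 8, again 1 of 10 each. For gene lists the values were 20 and 16 (1 of 10), 16 and 11 (1 of 10), and 16 and 16 (2 of 10). Up to 16, 11 and 16 lists thus passed in splits that called at most 9, 17 and 8 rows. A camera call at the preset correlation therefore does not by itself mark the real groups. Of 100 splits of the 9 libraries into 3 groups, 2 gave at least 633 rows higher in both and 2 gave at least 1355 lower in both, the real one included each time. Chance division of these libraries can be excluded at 0.05, which shows that the groups of libraries differ and not that the constructs share changes. As the replicates may be technical, this does not tell an effect of a construct from a difference between single cultures. The other split, with 2469 and 3091 rows, took all 3 Halo-RelA libraries as the control, which points to a structure of the samples and is what a control that stands apart gives.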

How the results depend on the processing

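Protein-coding rows alone, library weights, depth as a covariate, RELA zeros as missing and the family list without RELA and NFKB1 were alternatives chosen after the data were seen. Of 315 named gene results past the threshold, 273 stayed past it with the same direction in all alternatives run, and of 52 list results 9 did, or 41 apart from the estimated correlation. The named genes were mostly picked for large differences or small adjusted p, so their share does not describe called rows in general. Counts of rows moved by over 1.5 times with a minimum fold of 1.5, to 3592 for Halo-RelA, 306 for Halo-NfkB1 and 3206 for the direct comparison, because fewer rows can pass. The Halo-NfkB1 count was 816 at a threshold of 0.01 and 1764 with the 2 groups alone, where fewer libraries set the spread. Lists past the threshold with an estimated correlation in camera were 3, 0 and 6; for the 0, 10 lists had an unadjusted p under 0.05 and fry passed 14. Rows higher in both were 407 without the filter and 354 with the 2 groups alone, and rows lower in both were 828 under quantile normalization and 893 with the 2 groups alone; the cause was not tested. Leaving out each library gave 8022 to 8694 rows for Halo-RelA, 1358 to 2636 for Halo-NfkB1, 6726 to 7053 for the direct comparison, 312 to 609 higher in both and 689 to 1366 lower in both, and 18 to 20, 15 to 16 and 16 to 16 lists past the threshold. The Halo-NfkB1 count was 1585 without Halo replicate 1, 1562 without Halo-NfkB1 replicate 1 and 1358 without Halo-NfkB1 replicate 3; rows higher in both were then 351, 312 and 348, and lower in both 784, 837 and 689. The RELA log2 difference of 2.90 ranged from 0.14 to 8.35 over these fits, reached 8.35 without Halo-RelA replicate 3, and was 8.35 with RELA zeros as missing, as the value listed at 0 sets it. Among lists past the threshold, the test direction turned for the proteasome list in Halo-RelA under quantile normalization (median -0.00052, adjusted p = 0.557), and the cause was not tested. It also turned for the NF-kB and IkB family in Halo-NfkB1 under fry (median 0.451, adjusted p = 0.114), where the NFKB1 value listed at 0 sets the mean. Medians of lists not past the threshold also changed sign under quantile normalization. These were S phase in Halo-NfkB1 (0.032) and, in the direct comparison, the IKK complex (-0.067) and ribosomal proteins (0.027).

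No pairing by replicate number was seen. None of the 9 same-numbered pairs correlated over 0.1 in their deviations from the group means (-0.07 to 0.06). Of 9 libraries, 4 correlated best with their own number. Pairs with other numbers ranged from -0.099 to 0.097. The highest of these joined Halo replicate 2 and Halo-RelA replicate 3, the deepest libraries of their groups. Differences in depth could hide a weak pairing, so shared cultures or days are not excluded. With the replicate number as a block (replicate block) the counts were 8690, 2107 and 7428, and lists past the threshold 20, 16 and 16. Depth ranged 3.71-fold between libraries, and differences of 0.5 on the log2 scale were found in 58.2% to 61.2% of simulated cases. Those cases were drawn among rows with higher means in Halo.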

Other observations

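SNORD87, a small nucleolar RNA, was at 164 ± 25.1 FPKM (SD, n = 3) in Halo and was listed at 0 in 2 of the 3 Halo-RelA libraries, and the call ended without Halo-RelA replicate 1 (adjusted p = 0.0508) or replicate 2 (0.0529). The calls of other short non-coding RNAs as lower with Halo-RelA also ended in part of the alternatives. The largest adjusted p over all alternatives was 0.125 for RNU6-834P, 0.0957 for RNU4-32P, 0.0628 for RNU6ATAC35P and 0.0735 for SNORA11G, and with the replicate number as a block the values of the first pair were 0.0789 and 0.0568. NME2, a nucleoside diphosphate kinase gene that overlaps a readthrough gene, was at 55.5 ± 12.8 FPKM in Halo, 6.84 ± 9.51 in Halo-RelA and 34.7 ± 3.07 in Halo-NfkB1. Its call between Halo-RelA and Halo-NfkB1 ended with a pseudocount of 0.1 (adjusted p = 0.0525), with the 2 groups alone (0.0693), without Halo-RelA replicate 2 (0.0697) and without Halo-NfkB1 replicate 1 (0.0672), 2 (0.0683) or 3 (0.0594). FSIP1 was at 14.7 ± 7.61 FPKM in Halo, 0.708 ± 0.481 in Halo-RelA and 0.894 ± 0.481 in Halo-NfkB1 (SD, n = 3), lower in both with a wide spread in Halo. The peptide hormone gene APLN was at 1.99 ± 0.315, 0.655 ± 0.160 and 0.743 ± 0.287 FPKM, and its call with Halo-NfkB1 ended without Halo replicate 1 (adjusted p = 0.0579) or Halo-NfkB1 replicate 3 (0.0564).

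RELA alone would take 25.5% and 27.6% of the estimated fragments of Halo-RelA replicates 1 and 2. These shares come from its FPKM and its longest annotated transcript of 3183 bases. FPKM are per mapped fragment, so such shares bear on the scaling of all other rows in Halo-RelA. If they lowered all other rows by a common factor, upper-quartile scaling would take it out. Relative to all rows, that scaling left 0.974 of the ribosomal and 0.969 of the oxidative phosphorylation median. This argues against a common factor as the whole cause of the falls of these lists. The part of these shares in other falls against Halo was not tested. The median log2 difference of all rows was -0.072 as deposited and -0.028 with upper-quartile scaling. The ribosomal median was -0.34 and -0.29 in these fits. Relative to all rows, quantile normalization left 0.0625 of it.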
